A study of Oryzias latipes with 36 samples.

How the data were processed

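Gene expression was measured in female medaka (Oryzias latipes), a small fish whose breeding follows day length, while fish held on short days (SD) were moved to long days (LD). Per the labels, the tissue was the lower telencephalon together with hypothalamus and pituitary. Fish were sampled every 4 h for 3 days at ZT4, ZT8, ZT12, ZT16, ZT20 and ZT24, where ZT is the time of day in hours as the labels give it. Day 0 was the last SD day, and days 1 and 2 were the first LD days, which makes 18 time points. Per the labels' protocols, each time point had 2 pools of 3 fish, RNA was extracted with a QIAGEN RNeasy kit, and Cy3-labelled RNA from the Agilent Low Input Quick Amp kit was hybridised to 36 single-colour arrays. The hours of light per day, lighting times and water temperature are not given in the sources used here, and no fish stayed on SD during days 1 and 2.

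Per the file headers, the authors exported an Agilent single-colour experiment as 1 raw and 1 normalized column per time point. The values of the 2 arrays of a time point were therefore not available separately, and a single time point has no replicate error here. The raw columns hold linear probe intensity as deposited by the authors, from 2.17 to 437743 over probes. The normalized columns hold log2 values as deposited: raw log2 intensity plus 1 constant per column, close to minus the column's 75th percentile, plus 1 constant per probe. After both constants the largest residual was 2.05e-06. Scanner software, background correction and the way the arrays of a time point were combined are not given in the sources used here. The number of arrays limits the precision, and probes near the lowest raw values carry little signal over background.

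The deposited log2 values were tested, each probe put back on its mean raw log2 level, which changes no difference between time points. The 60 control spots were left out, which left 31090 probes. Gene symbols and names are those of the table, with 257 symbols filled or replaced through accessions of the reference gene table (assembly ASM223467v1), in which 15806 probes were matched. A usable gene name was held by 23726 probes, for 18797 distinct genes. Many genes have only a LOC number as symbol and are given with the table's name in parentheses. A gene was represented by its probe with the highest mean signal. Probes in the lowest 30% of mean signal, at a raw intensity of 61.6 or less, are called dim.

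The design written before the data were examined assumed 36 separate arrays. With 1 value per time point, the tests were adapted. Day effects and time of day were tested in limma (3.58.1, R 4.3.3, lmFit and eBayes) with additive terms for day and ZT, which leaves 10 residual degrees of freedom, so the error is the spread of time points around that model. Time of day was an F test of the ZT terms. A 24-h rhythm was an F test of cosine and sine terms beside day, with 13 residual degrees of freedom. The interaction of day and time of day was an F test of separate cosine and sine terms per day, with 9 residual degrees of freedom. Differences at single ZTs have no test and are given as values. Benjamini-Hochberg adjustment ran over all probes, and calls have an adjusted p under 0.05. Standard errors (SE) are those of limma, and every day difference rests on 6 time points per day.

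Before the data were examined, 26 gene lists were fixed by symbol, and 25 had at least 5 measured genes. Most listed symbols also matched with a suffix such as a, b or l, which can bring in a gene of another kind. They were tested with limma's camera at a preset correlation of 0.01, beside the estimated correlation and fry, with adjustment over lists within each comparison. Only the camera results are given below. Enrichment of rhythmic genes in a list used a one-sided Fisher's exact test among 20347 represented genes. Because many medaka genes carry only LOC symbols, lists extended by the table's gene names were added after the data were seen. Also fixed before the data were examined were the alternatives for normalization, filter, variance model, weights and left-out time points. The rule for the genes named was fixed then too, and covers probes with a gene name. It took the 12 largest called rises and falls on day 1 and on day 2 with the same sign at 5 or more of 6 ZTs. It also took the 5 largest of day 2 against day 1, the 15 largest time-of-day ranges and the 10 smallest interaction p. Further parts were the 3 largest differences past the threshold at each ZT, leading members of every list, and a set of clock and hormone genes whatever their values. At single ZTs no test was possible, so dim probes were left out in place of the threshold. That filter was not in the rule as fixed. Leading members of a list are given for the day 2 comparison or for the rhythm, and for day 1 where the list as a whole moved. A member of the circadian clock list that this rule names, and the counts of that list on day 2 as fixed, are not reported here.

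Control spots showed that the time points fall into 2 sets of arrays, up to 16 h after the transition (10 time points) and from 20 h on (8 time points). The labels name no such batch. The set was added, after the control spots were seen, as a block in every fit, and day comparisons were repeated within a set where both days had time points.

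On simulated data with 200 of 31090 probes changed 2-fold, 84.5% were recovered for day 1 against day 0, 80.5% for day 2 against day 0, 82.0% for day 2 against day 1, 61.0% for time of day and 85.5% for the 24-h rhythm. For the interaction, 9.0% were recovered at 2-fold and 60.0% at 4-fold. Of 20 shifted lists camera called 20, and of 20 unshifted lists 0. The simulated noise was independent between probes and held no array sets or drift, so the simulation does not test the preset correlation. Data were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.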

Results

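Signals of 31090 probes were compared over 18 time points, 6 per day, on the last SD day (day 0) and the first 2 LD days (days 1 and 2). Each time point has 1 deposited value from 2 pools of 3 fish. The 75th percentile of raw intensity lay between 765 and 1097 over time points. Hormone transcripts read far above background: mean raw intensity was 80838 for prolactin-1 (LOC101172582), 28257 for cga, the shared subunit of the glycoprotein hormones, 27362 for growth hormone (LOC101171460, somatotropin), 14909 for lhb and 8076 for the thyrotropin subunit beta (LOC101171658). The first principal component took 29.0% of the variance and went from -54.2 at the first time point to 40.3 at the last, with a step from -4.95 at 16 h to 31.3 at 20 h and a return to 9.87 at 32 h. A control spot without fish RNA, the bright corner, was higher from 20 h after the transition on, and the time points up to 16 h and from 20 h on are called the first and second array set here.

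**Figure D1:**
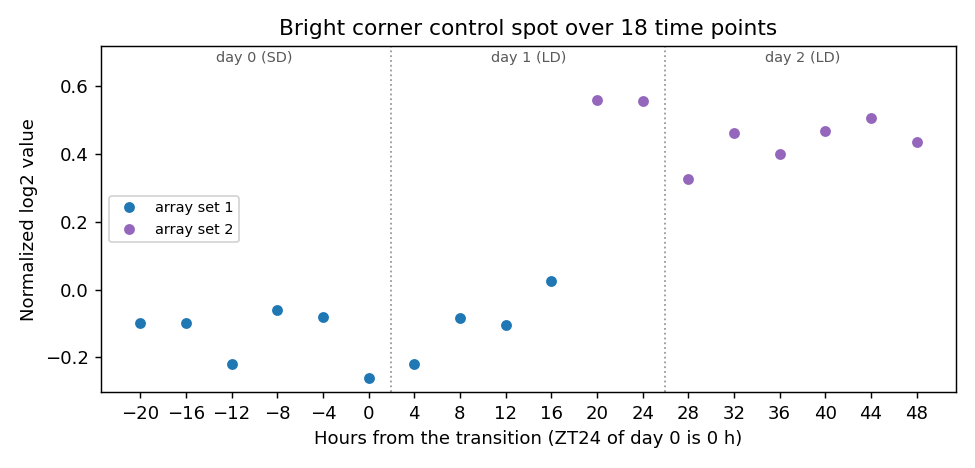
Normalized log2 value of the bright corner control spot against hours from the transition, 1 point per time point. Values of the second array set, 0.33 to 0.56, lie above those of the first, -0.26 to 0.03.

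The first question is which genes follow the time of day in this brain region. Core genes of the circadian clock were among those with the largest swings. The ciart-like repressor LOC101172421 (circadian-associated transcriptional repressor) ranged 16.6-fold between its highest and lowest ZT mean, with a fitted peak at ZT 0.842 (adjusted p = 2.4e-07 for the rhythm; dim, mean raw intensity 53.6). Its relative LOC101157319 ranged 6.20-fold and peaked at ZT 0.295. The receptors that repress bmal1, LOC101174341 and LOC101173939 (nuclear receptor subfamily 1 group D member 1), ranged 11.1-fold and 8.11-fold with peaks at ZT 19.0 and ZT 20.5. The bmal1-type activators LOC101174183 and LOC101159313 (aryl hydrocarbon receptor nuclear translocator-like) peaked at ZT 13.2 and ZT 12.1, and the clock gene itself, LOC101165450 (circadian locomoter output cycles protein kaput), at ZT 11.9 with a range of 1.93-fold. LOC101174183 is dim, with a mean raw intensity of 44.0. Of the period repressors, per1 peaked at ZT 1.40 (5.75-fold, adjusted p = 1.2e-08), the per3 gene LOC101159817 at ZT 3.16 (6.58-fold, adjusted p = 7.7e-10) and per2 at ZT 8.02 (4.93-fold, adjusted p = 0.0044).

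**Figure D2:**
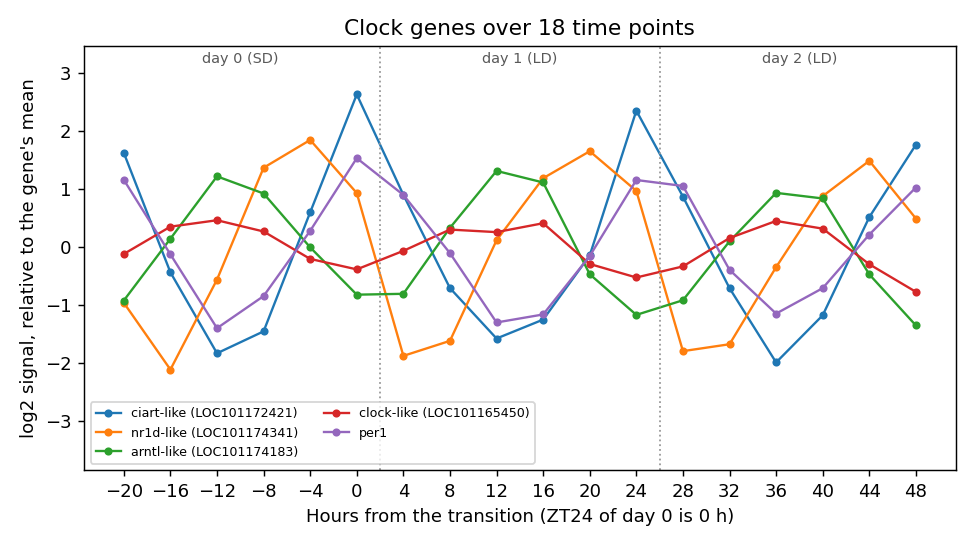
log2 signal of 5 clock genes, each relative to its own mean, against hours from the transition, 1 point per time point. Activators (LOC101174183, LOC101165450) are high near ZT12 on each of the 3 days, when per1 and the ciart-like gene are low.

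Genes driven by the clock were among the largest swings too. These were the CLOCK-interacting pacemaker-like LOC101157237 (range 9.54-fold, peak ZT 1.48), the hlf-like transcription factor LOC101163688 (9.18-fold, ZT 23.3), the nfil3-like factor LOC101175377 (6.86-fold, ZT 11.3) and bhlhe41 (7.04-fold, ZT 0.386). Of these, bhlhe41 is dim, with a mean raw intensity of 40.2. The cytochrome P450 genes LOC101156965 and LOC101156566 (cytochrome P450 2J6-like and 2J6), which oxidise fatty acids, ranged 10.1-fold and 9.75-fold and peaked at ZT 6.52 and ZT 6.57. The splicing factor gene LOC101168770 (SMU1) ranged 7.98-fold and lonrf3, a ubiquitin ligase, 7.66-fold. The dim purpurin-like LOC101155944 ranged 15.1-fold but did not follow a 24-h cosine (adjusted p = 0.27), and LOC101163197 (chromatin modification-related protein eaf-1-like) ranged 6.23-fold beside its fall over the series described below. Further clock genes with a rhythm were the group D member 2 receptors LOC101156434 (3.03-fold, peak ZT 2.09) and LOC101163230 (3.51-fold, peak ZT 2.35), cry1ba (4.31-fold, peak ZT 9.79) and the cryptochrome-1-like LOC101167667 (2.16-fold, peak ZT 7.52), LOC101174986 (5.95-fold, peak ZT 5.79) and LOC101160902 (1.44-fold, peak ZT 0.537). The per2-like LOC101161338 (adjusted p = 0.069) and the cry1-like LOC101164536 (adjusted p = 0.095) missed the threshold for a rhythm, as did the bmal-type LOC101175041 (adjusted p = 0.19).

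In all, limma called 648 probes for time of day and 2558 for a 24-h rhythm, of which 615 were called by both. Rhythmic probes had a median peak-to-trough ratio of 1.33-fold, and the ZT12 to ZT16 window held the most peaks, 644 probes or 25.2%. With the array set as a block, 1745 probes were called rhythmic, of which 1626 were among the 2558. Within day 0, day 1 or day 2 alone limma called 0 probes, with 4318, 2594 and 2700 at an unadjusted p under 0.05.

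Among the fixed lists, 4 held more rhythmic genes than the represented genes as a whole. The circadian clock list had 7 of 11 (9 adjusted over the list alone; Fisher adjusted p = 3.2e-04), and 31 of 38 once genes were also matched by name (36 adjusted over the list alone; adjusted p = 9.0e-25). The list for light-induced genes and photolyases had 5 of 7 (6 adjusted over the list alone; adjusted p = 9.6e-04), led by catalase (cat, peak ZT 15.7), lonrf1 (peak ZT 7.40) and heme oxygenase hmox1 (peak ZT 15.3). With the array set as a block lonrf1 was not called (adjusted p = 0.052), and neither was ddb2, another of the 5 (adjusted p = 0.091). The unfolded protein response of the endoplasmic reticulum, which folds secreted proteins such as hormones, had 9 of 22 (12 adjusted over the list alone, Fisher adjusted p = 9.1e-04). The chaperones hsp90b1, pdia4 and manf peaked at ZT 13.3, ZT 14.6 and ZT 13.3 with peak-to-trough ratios of 1.40, 1.28 and 1.60. The sensor gene atf6b, which is dim (mean raw intensity 41.0), peaked at ZT 2.27. Heat shock and cold response had 7 of 16 (9 adjusted over the list alone, Fisher adjusted p = 0.0018). Among them were the co-chaperone dnaja4 at ZT 11.2 (3.53-fold) and hsf2 at ZT 1.64 (2.96-fold, dim, mean raw intensity 26.1). The collagen chaperone serpinh1 peaked at ZT 6.69 (1.78-fold) and the cold-inducible cirbp at ZT 17.7 (1.35-fold).

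Other lists did not pass this test. Immediate early genes had 5 of 20 (7 adjusted over the list alone; adjusted p = 0.15), with dusp5, jund, fosl2 and fosb all peaking between ZT 8.07 and ZT 9.16. Of these named genes, only jund stayed called with the array set as a block (adjusted p = 0.042). The others had adjusted p = 0.054 (dusp5), 0.057 (fosl2) and 0.0997 (fosb). Sterol synthesis had 4 of 20 (9 adjusted over the list alone; adjusted p = 0.43), led by idi1 at ZT 15.3 and dhcr7 at ZT 6.61. Stress and glucocorticoid genes had 2 of 17 (4 adjusted over the list alone), hsd11b1l and sgk1, of which sgk1 was not called with the array set as a block (adjusted p = 0.079). Hypothalamic neuropeptides had 2 of 20 (4 adjusted over the list alone), nmb at ZT 9.86 and vip at ZT 13.0. With the array set as a block neither stayed called (adjusted p = 0.16 and 0.085). The thyroid and photoperiod list had 3 of 17 (3 adjusted over the list alone): eya4, TSHR and dio3. Of these, dio3 was not called with the array set as a block (adjusted p = 0.067), and TSHR is dim, with a mean raw intensity of 22.8. Pituitary hormones had 0 of 13 called by limma and 0 adjusted over the list alone, and fshb with the largest range of them moved 2.35-fold between ZT means (adjusted p = 0.13 for time of day).

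The next comparison asks what changed on the first LD day against the last SD day at matched ZTs. The main change was a joint fall of a set of genes that includes those of the egg coat. The ZPC and zona pellucida genes, whose proteins form the coat of the oocyte, were among the 12 largest falls: ZPC domain containing protein 3 (LOC100049335) -2.97 (SE 0.41, adjusted p = 0.0062), ZPC domain containing protein 1 (LOC100049333) -2.93 (SE 0.40, adjusted p = 0.0062) and the zona pellucida sperm-binding protein 3-like LOC101168341 -2.87 (SE 0.40, adjusted p = 0.0063). Among genes with a name, to which all rankings by size here are limited, the largest fall was that of the hornerin-like LOC101171217, a log2 difference of -3.01 (SE 0.41, adjusted p = 0.0062).

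The other members of the 12 largest falls on day 1 lay between -2.95 and -2.78, each in the same direction at 6 of 6 ZTs: LOC101171467 (FH2 domain-containing protein 1-like), LOC101163197 (chromatin modification-related), the hornerin-like LOC101170975 and LOC101168022, LOC101169148 (YEATS domain-containing protein 2-like), LOC101161987 (claudin-like ZF-A89), LOC101158670 (ubinuclein-1-like) and LOC101156256 (serine protease inhibitor A3N-like). The fall began before the transition. ZPC domain containing protein 1 (LOC100049333) read 3970 raw units at ZT4 of day 0, 402 at ZT24 of day 0, 224 at ZT16 of day 1 and 41.1 at the last time point, and choriogenin H (LOC100049432), an egg coat protein made in the liver, read 4203, 642 and 436 at the first 3 of these times. Over the 137 probes called lower, the median changed by -3.35 log2 from the first to the last time point of day 0.

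**Figure D3:**
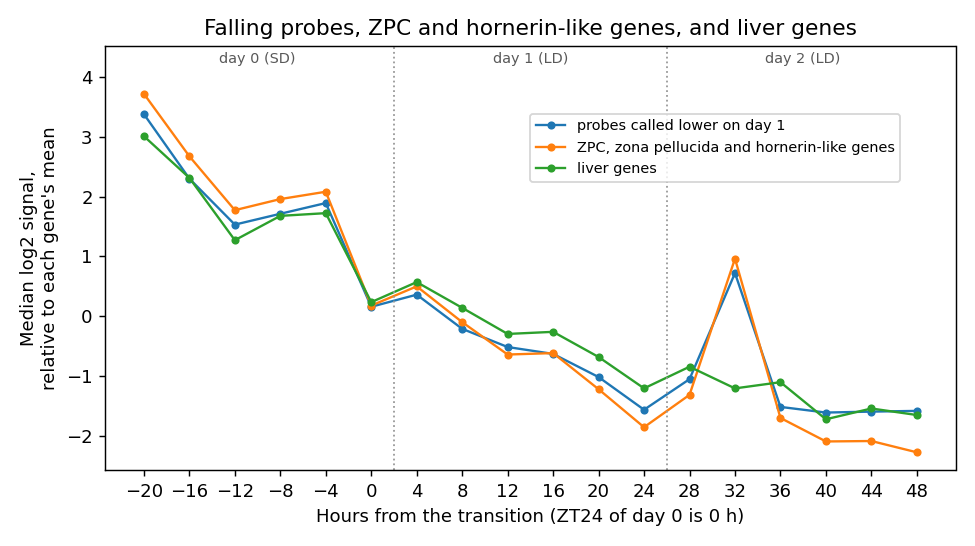
Median log2 signal, relative to each gene's mean, of the 137 probes called lower on day 1, of 11 ZPC, zona pellucida and hornerin-like genes and of 8 liver genes (vitellogenins, choriogenin H, L-SF, fgb and hpx), against hours from the transition. The 2 gene groups were chosen after their values were seen. The first was taken from probes called lower on day 1, and the liver genes from genes called lower on day 2, which includes 32 h. All 3 lines are highest at the first day 0 time point, and at 32 h the first group stands at 0.96 and the liver genes at -1.20.

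Rises on day 1 were smaller and mostly in dim probes. The largest among named genes was the olfactory receptor 52R1-like LOC101174006, by 2.85 (SE 0.53, adjusted p = 0.033, raw intensity 4.04 on day 0 and 30.3 on day 1), followed by the neurotrophin receptor LOC101168685 (NT-3 growth factor receptor-like, 1.47), LOC101160429 (claudin-4-like, 1.25), LOC101167461 (homeobox protein Nkx-3.1-like, 1.05), inha, a subunit of the hormone inhibin (1.00), and MSX2 (0.95). For dim probes near background on day 0, such as these, the size and order of the rises are not exact. Only eps15l1a, an endocytosis gene (0.89, SE 0.16, adjusted p = 0.029), and LOC101161096, a glutathione peroxidase 1-like antioxidant gene (0.81, SE 0.15, adjusted p = 0.036), stood above the dim level among the 12 largest. The remaining ones, LOC101172852 (vegetative cell wall protein gp1-like), the lin-28 homolog LOC101169811, mir196a and tnfrsf19, rose by 0.73 to 0.77. In all, 198 probes were called, 61 up and 137 down, and 7 rises and 130 falls were at least 2-fold. The balance rests on single time points: without ZT4 of day 1 it was 194 up and 127 down, and without ZT20 of day 1 it was 9 up and 84 down. Within the first array set, over ZT4 to ZT16, 107 probes fell and 8 rose, and 97 of the 137 falls were among them. With the array set as a block 34 probes were called (5 up, 29 down).

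Genes of the photoperiod pathway and the pituitary did not pass on day 1. The thyrotropin subunit beta LOC101171658, the seasonal signal of the pars tuberalis in birds and mammals, differed by 0.14 (adjusted p = 0.77), its dim paralog LOC105354380 by -0.41 (adjusted p = 0.87), cga by 0.41 (adjusted p = 0.43), dio2 by -0.02 (adjusted p = 0.98), dio3 by 0.17 (adjusted p = 0.42), the deiodinase LOC101170321 by -0.04 (adjusted p = 0.89), eya3 (LOC100049216) by 0.04 (adjusted p = 0.86), fshb by 0.25 (adjusted p = 0.58), lhb by 0.50 (adjusted p = 0.44), growth hormone (LOC101171460) by 0.06 (adjusted p = 0.95), prolactin-1 (LOC101172582) by 0.28 (adjusted p = 0.39), prl by 0.18 (adjusted p = 0.94) and crhr2 (LOC101157488) by 0.07 (adjusted p = 0.78). The LPIN2-like genes LOC101174419, LOC101161835 and LOC110017258 lay between -0.04 and 0.06. Across fixed lists, camera called the marker list for liver, ovary and yolk lower (9 genes, median -0.40, adjusted p = 0.022; adjusted p = 0.47 with an estimated correlation; 1 gene called, fgb at -2.13, and 1 adjusted over the list alone). It also called the cell cycle list lower (29 genes, median -0.12, adjusted p = 0.0047; adjusted p = 0.93 with an estimated correlation), led by the mitotic cyclins ccnb2 (-0.87, adjusted p = 0.19) and ccnb1 (-0.69, adjusted p = 0.31), though limma called 0 of its genes (0 adjusted over the list alone). Both lists were also lower within the first array set at the preset correlation, at adjusted p = 6.9e-04 and 1.0e-09. These time points are part of the same comparison, and the estimated correlation was not run there, so the 2 values are no separate support. With genes matched by name, the liver, ovary and yolk list held 34 genes, 12 of them called lower (15 adjusted over the list alone; adjusted p = 1.5e-14; adjusted p = 0.13 with an estimated correlation).

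The comparison of the second LD day with the last SD day asks the same after a full day of long light. The 12 largest falls again held ZPC and hornerin-like genes, with liver genes of egg production beside them. Among named genes, falls were led by LOC101169148 (YEATS domain-containing protein 2-like), -4.35 (SE 0.43, adjusted p = 1.5e-04), hornerin-like LOC101171217, -4.25 (SE 0.41), ZPC domain containing protein 1 (LOC100049333), -4.16 (SE 0.40), choriogenin H (LOC100049432), -3.87 (SE 0.19, adjusted p = 3.3e-06) and the yolk precursor vitellogenin II (vit-6), -3.69 (SE 0.20, adjusted p = 3.4e-06). The other falls among the 12 largest lay between -4.15 and -3.54: LOC101171467, LOC101170975, LOC101163197, LOC101156256, LOC100049335, LOC101168341 and ZPC domain containing protein 5 (LOC100049337). The largest rises among named genes were zmpste24, which processes the nuclear protein lamin A (5.14, SE 0.48, adjusted p = 1.1e-04; dim, mean raw intensity 31.5), and prr18, a proline-rich gene above the dim level (3.03, SE 0.28, adjusted p = 1.1e-04, mean raw intensity 192).

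The sizes of rises in dim probes, zmpste24 included, are not exact here either. The other rises among the 12 largest were all dim and lay between 2.05 and 2.89: LOC105354733 (leucine-rich repeat transmembrane protein), palm2, LOC101168462 (FAM57B), SH3GL2, an endocytosis gene of synapses, the potassium channel subunit LOC101172249, LOC101165093 (C-reactive protein-like), LOC101168685, LOC101155124 (proteasome subunit beta type-8-like) and the olfactory receptor-like LOC101162546 and LOC101174006. In all, 7663 probes were called, 4631 up and 3032 down (3631 and 4018 after quantile normalization), with a median size of 0.36 log2, and 508 rises and 182 falls were at least 2-fold. All day 2 time points lie in the second array set and all day 0 time points in the first, and with the set as a block 11 probes were called (6 up, 5 down). Of the genes named here, only choriogenin H (LOC100049432, -3.43), vitellogenin II (vit-6, -3.09) and L-SF (1-sf, -2.95) stayed called with the block, each at adjusted p = 0.028. The other day 2 calls given here, hormone genes and list members included, were not called with it.

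Prolactin-1 (LOC101172582), which regulates salt and water balance in fish, rose by 0.45 on day 2 (adjusted p = 0.032; 0.26 and adjusted p = 0.91 with the block), while LOC101171658 (0.35, adjusted p = 0.15), cga (0.38, adjusted p = 0.23), fshb (0.36, adjusted p = 0.17), lhb (0.34, adjusted p = 0.40), LOC101171460 (0.30, adjusted p = 0.49), prl (-0.79, adjusted p = 0.49), LOC105354380 (-1.11, adjusted p = 0.35), dio2 (-0.20, adjusted p = 0.47), dio3 (0.25, adjusted p = 0.063), LOC101170321 (-0.04, adjusted p = 0.76), eya3 (LOC100049216, 0.10, adjusted p = 0.40) and crhr2 (LOC101157488, 0.24, adjusted p = 0.052) did not pass. The LPIN2-like genes lay between -0.12 and 0.20. Of the clock genes, the bmal-type LOC101175041 (0.73, adjusted p = 0.0079), the cry1-like LOC101164536 (0.50, adjusted p = 0.0053) and LOC101160902 (0.31, adjusted p = 0.010) were called, and hlf-like LOC101163688 fell (-0.37, adjusted p = 0.024).

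Camera called none of the 25 tested lists on day 2 (lowest adjusted p = 0.078, ribosomal proteins). With the array set as a block it called liver, ovary and yolk lower (adjusted p = 0.026); an estimated correlation was used only without the block, where it gave adjusted p = 0.99. With genes matched by name it called that list lower too (34 genes, median -0.29, adjusted p = 6.0e-05; adjusted p = 0.56 with an estimated correlation; 2 up and 13 down, 3 and 14 adjusted over the list alone), and ribosomal proteins (adjusted p = 0.041; adjusted p = 0.99 with an estimated correlation). The counts that follow are over all probes, with those adjusted over the list alone after them. Of all probes 24.6% were called on day 2, so a count near that share of a list is no sign of a change in the list. The lists below held 17 thyroid and photoperiod, 14 reproductive, 20 neuropeptide, 13 pituitary hormone, 17 stress, 20 immediate early, 7 light-induced and 6 opsin genes. In the circadian clock list timeless rose (0.60) and rora (-0.15, adjusted p = 0.053) missed the threshold, and with genes matched by name 5 of 38 were up and 4 down against the same counts. In the thyroid and photoperiod list the melatonin receptor mtnr1a (0.15) and tshr (0.49) rose, 2 up against 0. In the reproductive neuroendocrine list the estrogen receptors esr2 (0.75) and esr1 (0.31) and fshr (0.60) rose, 3 up against 3. Among hypothalamic neuropeptides oxt (-0.40) and nmb (-0.54) fell and hdc (0.25) rose, 1 up and 2 down against the same counts. Pituitary hormones had 0 calls in limma and 0 over the list alone, led by pomc (-0.30, adjusted p = 0.070). Stress and glucocorticoid genes had 2 down against 0, errfi1 (-0.16) and nr3c2 (-0.29). Immediate early genes had 2 up against 2, nr4a1 (0.45) and nr4a2 (0.20). Light-induced genes had 0 in limma and 0 over the list alone, led by neil1 (-0.19, adjusted p = 0.087). Of the opsins, tmtops1b rose (0.45), 1 against 1. With genes matched by name, 7 of 21 opsin genes and 7 of 38 thyroid and photoperiod genes were up and 1 in each was down, against the same counts.

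Single genes were called in the lists of cell upkeep, again beside 24.6% of all probes. These lists held 16 heat shock, 22 unfolded protein response, 29 cell cycle, 20 sterol synthesis, 59 ribosomal and 28 respiration genes. Heat shock genes bag3 (0.67) and serpinh1 (0.45) rose and hspe1 fell (-0.19), 2 up and 1 down against the same counts. In the unfolded protein response manf (0.31) and sel1l (0.31) rose, 3 up and 1 down against the same counts. The cyclin ccne2 (0.76) was the 1 called cell cycle gene, and the same 1 over the list alone. In sterol synthesis sc5d rose (0.34) and insig1 fell (-0.23), 1 up and 2 down against 1 and 0. Ribosomal protein genes had 2 up and 7 down against the same counts, led by rps10 (0.90) and rps16 (-0.21). Mitochondrial respiration had 2 up and 6 down against 2 and 7, led by ndufb5 (0.33), ndufs7 (0.38) and, among the falls, ndufa2 (-0.23).

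Single genes were also called in marker lists of cell types, beside the same 24.6% of all probes. These lists held 17 neuron, 11 astroglia, 10 oligodendrocyte, 10 microglia and leukocyte, 13 endothelium, 16 dorsal brain, 16 photoreceptor, 7 lens, 8 muscle and 9 liver, ovary and yolk genes. The neuron markers slc17a6 (0.80) and stmn2 (-0.41) went apart, 2 up and 6 down against 2 and 7. Astroglia had 3 up against 3, led by vim (0.27), and oligodendrocytes 2 up and 1 down against the same counts, led by the myelin gene mbp (0.37). Microglia and leukocytes had 2 up and 1 down against the same counts, with the protease gene ctss at -3.47. Endothelium and meninges had 1 up and 1 down against 0, led by cldn5 (0.18). Genes of dorsal brain regions had 2 up and 6 down against the same counts, led by zic2 (-0.35) and cbln1 (-0.50). Photoreceptor and pineal genes had 1 up and 1 down against the same counts, with rho at 1.18 and rhob at -0.25. The symbol rhob matched only as rho with the suffix b, so this fall is not evidence on photoreceptor genes. Lens had 1 up against 1, bfsp1 (0.51), and skeletal muscle 2 up against 2, led by NEBL (0.44). NEBL is named nebulette and matched only as the listed neb with the suffix l, so its rise is not evidence on skeletal muscle. Erythrocytes had 1 measured gene, rhag (-0.12, adjusted p = 0.32). With genes matched by name the erythrocyte list had 8 genes, 3 of them up against 3, with a median of 0.29 (camera adjusted p = 0.32), and of -0.18 with the array set as a block. Liver, ovary and yolk had 1 up and 2 down against 1 and 3, with fgb at -2.55 and amh at 0.87. Both lie near background, with mean raw intensities of 12.8 and 10.0, so these sizes are not exact.

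Between the LD days, 4 genes of egg coat and yolk made in the liver were called lower. Choriogenin H (LOC100049432) fell by 1.62 (SE 0.19, adjusted p = 0.0028), L-SF (1-sf), an egg envelope subunit made in the liver, by 1.57 (SE 0.18, adjusted p = 0.0022), vit-6 by 1.56 (SE 0.20, adjusted p = 0.0049) and vitellogenin 1 (ol-vit1) by 1.06 (SE 0.21, adjusted p = 0.038). The liver, ovary and yolk list as a whole was not called (median 0.09, adjusted p = 0.91). The 5th largest fall was calpain-15 (LOC101157134, -0.52). The largest rises were zmpste24 (3.68), prr18 (2.61), LOC105354733 (2.31), LOC101172249 (1.99) and nanos2, a germ cell gene (1.91, dim). In all, 344 probes were called, 292 up and 52 down (133 and 69 after quantile normalization). The count rests on single time points, with 1750 probes without ZT24 of day 1, 87 without ZT12 of day 2 and 57 without ZT12 of every day. Lists called lower by camera were ribosomal proteins (median -0.03), neuron markers (-0.10) and mitochondrial respiration (-0.07), each at adjusted p = 0.045, and adjusted p = 0.98 with an estimated correlation, and none of the 3 was called lower with quantile normalization or with the array set as a block; adjusted over the list alone, limma called 0, 4 and 0 of their genes, against 0, 1 and 0 over all probes. With genes matched by name, camera called the opsin list higher (21 genes, median 0.21, adjusted p = 0.018; adjusted p = 0.10 with an estimated correlation). With the array set as a block its median was 0.08 (adjusted p = 0.076), and limma called 0 of its genes over all probes and 6 adjusted over the list alone. Within the second array set, over ZT20 and ZT24, limma called 0 probes, with 2615 at an unadjusted p under 0.05 and 1 residual degree of freedom. With the set as a block 10 were called, 8 up and 2 down, so not all 4 of the liver genes above kept their call.

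Did the response on day 1 resemble that on day 2? Of the 137 probes called lower on day 1, all 137 were also called lower on day 2, and 60 of the 61 rises were shared, where independent lists would share 13.4 and 9.09. Both comparisons use the same day 0 values. Across probes, which are not independent replicates, their differences correlated at 0.81, against 0.50 for simulated unchanged days, and their covariance was 0.085 against 0.014. With day 0 split so that each comparison used other ZTs, the correlation was 0.49 and 0.60 and the covariance 0.062 and 0.082. The simulated 0.50 and 0.014 hold for comparisons that share day 0 and are no reference for these split values. No unchanged days were simulated for the split. The simulated days carry no array sets, and ZT20 and ZT24 of day 1 share the second set with day 2, so these values include any difference between the sets. They also include any drift along the series that began before the transition. The median of the 137 falling probes went from 3.37 at ZT4 to 0.16 at ZT24 of day 0.

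At single ZTs, where there is no error estimate, differences of at least 2-fold on day 1 numbered between 990 probes (ZT16) and 1875 (ZT24), and on day 2 between 1520 (ZT20) and 2172 (ZT8). On day 1, ZT20 and ZT24 compare different array sets and held the highest counts, and on day 2 all ZTs do. Genes of the joint fall were among the 3 largest at several ZTs, such as LOC100049335 at ZT4 of day 1 (-3.46) and LOC101169148 at ZT4 (-5.72), ZT12 (-4.36) and ZT16 (-5.31) of day 2. Protamine (LOC100049429), a packaging protein of sperm, fell by 5.12 from ZT4 of day 0 to ZT4 of day 1. Other genes differed widely at some time points: coagulation factor VII-like LOC101154762 (6.03 at ZT24 of day 1, -5.81 at ZT12 of day 2), acmsd, an enzyme of tryptophan breakdown (-3.39 at ZT12 of day 1), and the glycosyltransferase gene LOC101161598 (-3.86 at ZT16 of day 1). Both acmsd and LOC101161598 had larger falls at other time points, some to values near background where no exact size holds. The low values behind the 2 differences of LOC101154762, 3.58 and 3.77 log2, are low too, so its sizes are not exact either. Rises at single ZTs included lect2 (3.39) and LOC105358776 (HTRA1-like, 3.81) at ZT8 of day 1, kallikrein-7-like LOC101163727 (3.68) at ZT16 of day 1, and the class I histocompatibility gene LOC101175175 (3.79) at ZT24 of day 2.

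The last comparison asks whether the daily profile itself changed with the LD days. The clearest shift to the eye was in light-responsive genes. On day 0 per2 read 1211 raw units at ZT4 and 1856 at ZT8, whereas on day 1 it read 2999.9 and 1775 and on day 2 it read 2326 and 1498. The cry1-like LOC101174986 went from 182 and 385 on day 0 to 882 and 239.8 on day 1 and 585 and 170.1 on day 2, and ddb2, a DNA repair gene, from 976 and 1665 to 1785 and 1604 and then 2099.9 and 1485. These genes were chosen after their values were seen, and the interaction test did not single them out (unadjusted p = 0.89 for per2 and 0.94 for LOC101174986). The genes with the smallest interaction p were LOC101173202, a dim runt-related transcription factor 1 gene (unadjusted p = 2.0e-05, adjusted p = 0.31), LOC101155975, a lysophosphatidylcholine transporter-like gene, bmp2k, LOC101163984, lmod2, LOC101170833, LOC101173993, LOC101156734, dbx2 and LOC101164931. Limma called 0 probes for the interaction, with 1887 of 31090 at an unadjusted p under 0.05, where a share of 0.05 is expected without any effect. By unadjusted p, cga (0.0070), LOC101171658 (0.015) and lhb (0.046) were among those 1887. None of them passed adjustment, so no change of their daily profile is shown.

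**Figure D4:**
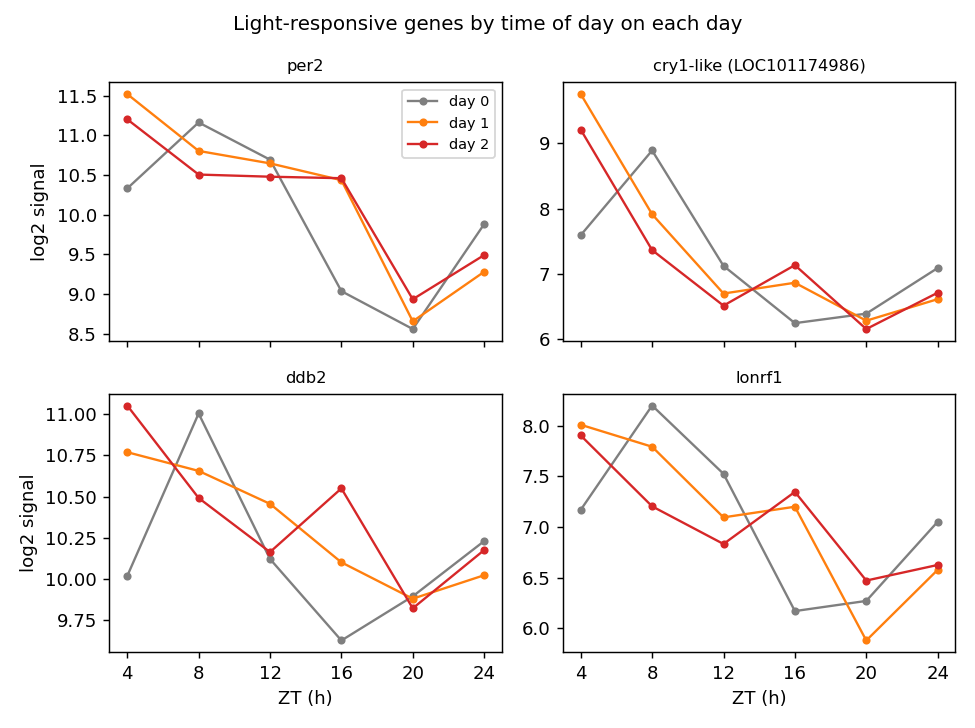
log2 signal of per2, the cry1-like LOC101174986, ddb2 and lonrf1 against ZT, 1 line per day and 1 point per time point. All 4 genes are highest at ZT8 on day 0 and at ZT4 on days 1 and 2.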

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

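Among the tests in this part, those of the egg and liver genes, the day 2 fit with the array set as a term, and the choice of array sets came after the results were seen.

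A signal in data outside the main measurement came first. The bright corner, a control spot that holds no fish RNA, was higher by 0.58 log2 from 20 h on than up to 16 h, with no overlap: up to 16 h it lay between -0.26 and 0.03, and from 20 h on between 0.33 and 0.56. Of the 60 control spots, 6 had separate ranges in these sets of time points. The break falls inside day 1 and not at the transition, and the spot is not read from the sample RNA.

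That break matters for the 7663 probes called on day 2. If arrays made the calls, the same probes would step up between days 1 and 2 at ZT4 to ZT16, which cross the sets, more than at ZT20 and ZT24, which do not. The medians were 0.25 and 0.066, a difference of 0.19 against a spread between ZTs of 0.030, which is consistent with a difference between the sets of arrays as a source of many of the calls. With the set as a term, the called probes kept a median of 0.47 of their difference, 0.104% of them stayed called, and the median SE grew from 0.083 to 0.15. That 0.47 lies under the bound of 0.5 written for this test as counting against a response to the LD days. The response is left open, a reading chosen after the value was seen, because the quartiles (0.18 and 0.81) span the bound and a response that began at 20 h would look alike. Response and arrays cannot be told apart for those probes. The count of 344 probes whose change differed between the LD days crosses the sets at 4 of 6 ZTs and stays open in the same way.

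The fall on day 1, which included egg and liver genes, was weighed next over all 137 falling probes, not all of which are egg or liver genes by name. A difference between the sets of arrays is argued against for these probes: within the first set, where no comparison crosses the sets, the median fall was 1.07 of that over all ZTs. The same time points helped to choose the probes, so the size of that share is not an independent test. A response to the LD days is argued against as the whole cause, because the falling probes had already changed by a median of -3.35 log2 within day 0, up to the transition. That value rests on 2 single time points: the medians over day 0 were 3.37, 2.30, 1.53, 1.71, 1.89 and 0.16, which leaves a fall of over 1 log2 without either end but not without both. RNA of ovary or liver in the pools, carried over at dissection in an amount that shrank along the series, stays open: the marker list fixed beforehand had a median of -0.45 within the first set, against -0.14 to 0.20 for the central 95% of 10000 random lists matched on signal, but camera had already called this list lower, so the comparison adds no independent evidence. Of its 9 genes 7 lay below 0 and fgb alone passed (adjusted p = 0.023). First values were 4203 raw units for choriogenin H (LOC100049432) and 3970 for ZPC domain containing protein 1 (LOC100049333). At 32 h the group of ZPC and hornerin-like genes stood at 0.96 and the liver genes at -1.20, apart from each other. The ZPC and hornerin-like group read -1.31 at 28 h and -1.70 at 36 h, so its signal did not shrink steadily. That rise rests on 1 time point. The liver genes were chosen among those called lower on day 2, which includes 32 h, so this choice may add to the distance. All 137 falling probes, the ZPC and hornerin-like ones included, were called lower on day 2 as well. None of the 9 genes of the marker list is in another list. Of them 8 lie near background, with mean raw intensities of 38.4 or less, which weakens the test, and foxl2, a gene also used in the pituitary, had 2332 and moved by -0.16. A change of reproductive state from day to day was not tested.

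Among 39 groups of 6 time points tested, with marker lists that include genes matched by name, 5 held a value far from the others, where about 1 in 20 is expected by chance. At ZT8 of day 2 the marker list for liver, ovary and yolk was high (0.15, the others from -0.24 to -0.11), the lens list low (-0.25, the others 0.04 to 0.16) and the erythrocyte list low (-0.13, the others 0.19 to 0.38). At ZT4 of day 0 the erythrocyte list was high (0.16, the others -0.34 to -0.20). The 75th percentile of raw intensity was high at ZT12 of day 2, 1097 against at most 978. No biological explanation was tested for these.

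Other assignments of the time points were counted for each test. Swapping days within ZTs gave as many calls in 1 of 32 splits, the real one, for each day comparison. The counts were 198 on day 1 against at most 1 in another split, 7663 on day 2 against at most 1573, and 344 between the LD days against at most 1. That is the lowest share that 32 splits can give. A drift over the series or a difference between the array sets would lower the other counts as well, so the splits do not tell the source of the calls. The split with 1573 swapped ZT16 alone. Shuffling ZTs within days gave as many in 1 of 100 splits, the real one, for time of day (648, highest other 5) and for the 24-h rhythm (2558, highest other 1). The random orders of ZTs drawn here thus did not give such counts. For the interaction, with 0 calls, 100 of 100 splits had to give as many, so the count says nothing about chance there; the highest other gave 20.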

How the results depend on the processing

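The array set as a block, comparisons within a set and lists extended by gene name were chosen after the data were seen. No paired analysis was possible because the table has 1 column per time point and no replicate numbers; this is about replicates, since the additive model matches days by ZT. For the same reason leaving out single arrays, the replicate block and fits within a replicate series were not run, and the additive model is the one reported.

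The day 1 count (198) moved to 111 without dim probes, 80 with probes averaged per gene, 34 with the array set as a block and 115 within the first set. Leaving out time points or ZTs gave 12 to 321: 12 without ZT20, 108 without ZT12, 125 without ZT8, 114 and 102 without ZT12 and ZT20 of day 0, and 321, 113, 93 and 126 without ZT4, ZT8, ZT20 and ZT24 of day 1. The day 2 count (7663) moved to 4426 per gene, 690 at 2-fold and 11 with the block, with 5103 to 8722 on leaving out (5103 without ZT12). Its share of rises, 60.4%, was 47.5% after quantile normalization, so the balance of rises and falls depends on scaling. The count between LD days (344, 84.9% up) moved to 202 (65.8% up) with quantile normalization, 97 without dim probes, 883 with array weights, 188 per gene, 50 at 2-fold, 77 in the 2 days alone, 10 with the block and 0 within the second set. It ranged from 57 (without ZT12) to 1750 (without ZT24 of day 1). Without ZT4, ZT8, ZT16, ZT20 or ZT24 it was 85, 141, 75, 127 and 967, without ZT12 or ZT20 of day 0 211 and 208, without ZT4 to ZT16 of day 1 112, 127, 103 and 104, and without each time point of day 2 132, 174, 87, 116, 180 and 154. The causes were not tested.

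Time of day (648) gave 342 with the block, 66, 36 and 53 without days 0, 1 and 2, where fewer time points were fitted, and 363 to 614 on leaving out; the lowest was without ZT24 of day 1. Without ZT8, ZT12, ZT20 or ZT24 of day 0 it was 399, 389, 390 and 422, without ZT4 to ZT20 of day 1 422, 379, 406, 406 and 382, and without ZT4, ZT12, ZT20 or ZT24 of day 2 412, 393, 411 and 369. The rhythm (2558) gave 1801 to 2797 on leaving out and 0 within each day. The interaction (0) gave 0 to 5 (5 without ZT8 of day 2, 1 without ZT16 or ZT24 of day 2). Differences of at least 2-fold at single ZTs, 18854 summed over comparisons, fell to 6237 without dim probes, which removes the probes nearest background.

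Lists called by camera numbered 5, against 0 with an estimated correlation (2 at unadjusted p under 0.05), 3 with quantile normalization, 3 with the block, 8 with extended lists, and 3 to 9 on leaving out ZTs (9 without ZT4, 3 without ZT8). Between LD days neuron markers had adjusted p = 0.34 with quantile normalization and 0.19 with the block, and mitochondrial respiration 0.38 and 0.70. Ribosomal proteins turned to a rise with quantile normalization (adjusted p = 0.98) and with the block (adjusted p = 0.70). Of 74 named genes with day 1 and day 2 differences, none changed sign while called. With the block, 21 lost a day 1 call and 42 a day 2 call. Within the first array set 11 lost a day 1 call, and with quantile normalization 5 did. For single genes the dim filter and array weights were not run, and of the fits that leave out time points only the lowest and highest are kept.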

Other observations

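The light test of this part was chosen before the values of its genes were seen, though after those of per2 and the cry1-like genes.

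The shift of per2 and the cry1-like genes from ZT8 on day 0 to ZT4 on LD days was noticed in the data. If light begins earlier relative to ZT on LD days, other light-induced genes of the list fixed beforehand would move the same way, and this test was written before their values were seen. The excess of ZT4 over ZT8 on LD days, less that on day 0, had a median of 0.57 log2 over its 7 genes, against -0.20 to 0.23 for the central 95% of 10000 random lists matched on signal. It was positive in 6 of 7, with 1.49 for lonrf1, 1.32 for ddb2, 0.63 for xpc, 0.57 for neil1 and 0.49 for hmox1, and -0.07 for catalase. For comparison it was 1.54 for per2 and 3.14 for the cry1-like LOC101174986. Each difference rests on single time points, among them ZT4 of day 0 and ZT8 of day 2, where some marker lists also stood apart from the other time points. Genes that move together would vary more than random lists do, so the range of those lists may be too narrow. The value of 0.57 is consistent with an earlier onset of light relative to ZT on LD days, as a hypothesis, since the lighting times are not given in the sources used here.

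Among clock genes, chosen after their values were seen, the bmal-type LOC101174183 was highest at ZT12 on each day, at 97.4, 123 and 97.7 raw units. The log2 signal of per1 was highest at ZT24 on days 0 and 1, at 14.62 and 14.24, and on day 2 it was 14.14 at ZT4 and 14.11 at ZT24.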
